A study of Homo sapiens with 48 samples.

How the data were processed

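Ribodepleted total RNA from SH-SY5Y lines was sequenced as paired fragments, and the study deposited count tables for genes, exon bins and introns. Per the submitters' processing notes, reads were aligned to hg19 with HISAT2 2.1.0 and counted with featureCounts from Subread, whose notes give version 1.6.5 and whose file header gives 1.6.3. The notes also name DESeq2 1.32.0, HOMER 4.11.1 and deepTools 3.2.1. The deposited values are raw counts per feature, not normalized, per the file headers. Gene counts cover the whole span of a gene, exons and introns together, per the file headers. A fragment that overlapped several features was counted for each of them. Counting was strand-specific while the labels' kit does not mark strand, so reads of antisense and overlapping genes cannot be told apart. The gene table holds 54630 rows, of which 2161 merge overlapping genes. Of its 57768 identifiers 51991 had a symbol in the reference table of gene names. The exon table holds 588114 bins and the intron file 220151 introns. No mitochondrial counts are present, so the list of mitochondrially encoded mRNAs could not be tested, and of the list of abundant non-polyadenylated RNAs only 2 genes could be tested.

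Each table has 54 columns from 9 line codes, against 48 labelled samples of 8 lines. The code wt was taken as wild type, e1 and e6 as the control clones, m3ko as the METTL3 knockout line, and kom8rem6 and kom8rem9 as the rescue clones (rem6 and rem9). Which code is clone 1 or 2 is not stated. Descriptions of the METTL3 knockout samples call them wild type; their titles were followed. For RBM45 knockout 3 codes stand for 2 labelled clones, so these 18 columns were not used and 36 were. The planned comparisons of RBM45 knockout clones were therefore not made. In their place the RA response of the rescue and METTL3 knockout lines, and exon bins and introns of the rescue lines, were added. They were chosen after column names, library totals, a principal component plot, correlations between libraries and the RBM45 and METTL3 values had been seen.

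Tests used R 4.3.3, edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr), limma 3.58.1 and DESeq2 1.42.0. A line was the unit. Its 6 libraries were summed for comparisons between lines, and its 2 libraries per medium for comparisons of media, with line as a block. All used lines shared the estimate of the spread. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The standard error of a log2 fold change was computed from the fold change and its F statistic. CPM values were computed from the deposited counts with TMM scaling, and log2 CPM with a prior count of 2. Exon bins and introns needed at least 10 counts in 2 line sums, and were tested with diffSpliceDGE. Introns were set against a summed exonic count of their gene.

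The 20 gene lists were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01 and at an estimated correlation, adjusted over 108 tests. Genes were named by a rule fixed before the data were examined: the targeted genes, up to 6 genes per direction with the largest log2 fold change that had a symbol, a mean of at least 1 CPM and the same direction in every line (or no overlap between the groups' libraries), up to 3 members per list, and up to 4 bins per direction with the smallest p. The values of 3 genes that this rule names are not reported here; they remain in the counts. That a symbol means exactly 1 symbol, how direction is read for the difference of RA responses, and a lookup of older histone symbols were settled after a look at the values. The division of RBM45 at its last bin and the METTL3 region were chosen after their values were seen; an earlier division of RBM45 that used fewer bins was also looked at. Intervals of shares are exact binomial (Clopper-Pearson, 95%). Where a medium held 1 to 3 counts of a gene, the ratio of the summed counts per scaled library size is given with its exact Poisson interval (95%), and a floor is 3 counts. These cover counting error only, since reads carry no molecular identifiers. The intervals of shares also take bin counts as independent, while 1 fragment can count in several bins. They may therefore be too narrow.

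Replicate libraries correlated at between 0.914 and 0.993 (log2 CPM, median 0.979). The lowest value, 0.914, was between the wild-type RA replicates, and the e6 GM replicates were at 0.925. The labels do not say whether replicates are separate cultures. The wild-type GM replicate 1 library had 1.07% of 82180000 fragments assigned to genes.

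The tests were tested on simulated data drawn from the real means and library sizes, with 67, 67 and 66 genes changed 2-, 4- and 8-fold. The changed genes, bins and introns were drawn only from those above a minimum mean count. Recovery among tested features with fewer counts was therefore not measured. For the rescue comparison 13.4%, 65.7% and 89.4% were recovered with 25 false calls, for METTL3 1.49%, 43.3% and 69.7% with 22, for RA against DMSO 53.7%, 98.5% and 98.5% with 16, and for DMSO against GM 55.2%, 94.0% and 98.5% with 13. The RA response of the rescue lines gave 14.9%, 67.2% and 92.4% with 12 false calls, and that of the METTL3 line 8.96%, 61.2% and 78.8% with 3. Exon bins gave 11.9%, 89.6% and 98.5% for the rescue lines with 26 false calls, and 2.99%, 70.1% and 90.9% for METTL3 with 11. Introns gave 11.9%, 74.6% and 100% for the rescue lines with 33 false calls, and 0%, 41.8% and 84.8% for METTL3 with 11. False calls made up more than the nominal 5% of all calls in each of these tests except the RA response of the METTL3 line, and changes of 2-fold were mostly missed in comparisons between lines. Alternatives covered DESeq2, no low-count filter, other units of replication, other normalization, wild type among the controls, leaving out each line or replicate number, and, chosen after seeing the data, lanes and leaving out the e6 and wild-type GM replicate 1 libraries.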

Results

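The series examined SH-SY5Y cells, a subline of the SK-N-SH neuroblastoma line that is used as a model of neuronal differentiation. RNA was ribodepleted and sequenced without selection for poly(A) tails. The labels describe 48 samples from 8 lines, namely wild-type cells, 2 control clones, 2 RBM45 knockout clones, 2 knockout clones with RBM45 restored (rescue) and 1 METTL3 knockout line. RBM45 is an RNA-binding protein and METTL3 is the catalytic subunit of the m6A RNA methyltransferase. Each line was sampled with 2 replicate libraries in each of 3 media. These were growth medium with serum (GM), serum-free differentiation medium with 0.1% dimethyl sulfoxide as vehicle for 7 days (DMSO), and the same medium with 10 µM retinoic acid for 7 days (RA). The stated aim was to follow RBM45 loss and restoration through neuronal differentiation.

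The values below come from 36 libraries of 6 lines. These were wild type, the control lines e1 and e6, the METTL3 knockout line, and the rescue lines rem6 and rem9, each with 6 libraries. The RBM45 knockout libraries were not analysed here, because the column names do not tie their 3 codes to the 2 labelled clones. Gene counts per library summed to between 888754 (wild type, GM, replicate 1) and 13417000 (rem6, RA, replicate 1), with a median of 8544920. The next lowest total was 3844960 (METTL3 knockout, GM, replicate 1). Libraries were run on lane 3 (wild type, e6, and part of rem9) or lane 4 (e1, METTL3 knockout, rem6 and the rest of rem9). Lane and line therefore overlapped. Within rem9 lane and medium overlapped too. Its GM libraries and DMSO replicate 1 were on lane 3, and DMSO replicate 2 and its RA libraries on lane 4. On lane 4 e1 was the only line without a targeted gene. Counts within lane 4 therefore rest on libraries of 1 such line, taken as samples.

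RBM45 (ENSG00000155636, hg19 chromosome 2, 178977151 to 179003738) separated the rescue lines from each other. Its level in rem9 was 527 ± 243 CPM (SD, n = 6 libraries), against 17.1 ± 2.64 in e1, 16.7 ± 2.73 in e6, 14.9 ± 3.62 in wild type and 17.4 ± 3.15 in the METTL3 knockout line. In rem6 it was 7.50 ± 1.52 CPM, below both control lines. These values count the whole span of the gene, introns included. Across both rescue lines the log2 fold change against the control lines was 3.90 ± 1.82 (SE, adjusted p = 0.375, edgeR), so the difference did not exceed the spread between lines. Without rem9 it was -1.16. Counts from the 18 RBM45 exon bins before the last bin (179001504 to 179003738, which holds the end of the gene) made up 88.7% of all RBM45 bin counts in e1 (95% exact binomial interval 86.2 to 90.9) and 91.9% in e6 (89.0 to 94.3). The share was 98.6% in rem6 (97.2 to 99.4) and 99.9% in rem9. Those 18 bins held 8.81 CPM in rem6, against 11.2 in e1 and 9.94 in e6, and 1015 in rem9. In rem6 the gap to the control lines was smaller there than in the last bin and the introns. A fragment that spans several bins was counted in each, so these sums are not numbers of fragments. They cannot be set against the CPM of the gene, and how far repeated counting changed this gap was not measured. The last bin held 0.127 CPM in rem6, 0.687 in rem9, 1.43 in e1 and 0.872 in e6. RBM45 introns held 3.00 CPM in rem6 and 3.56 in rem9, against 6.48 in e1 and 6.82 in e6.

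METTL3 (ENSG00000165819, chromosome 14, 21966277 to 21979517) was measured at 49.3 ± 4.11 CPM in the line labelled METTL3 knockout, 52 in e1 and 52.8 in e6 (n = 6 libraries each). The log2 fold change against the control lines was -0.06 ± 0.11 (SE, adjusted p = 0.995, edgeR), and with library replicate 2 alone its sign turned, at 0.00838. RNA abundance therefore does not check this label, since an edited gene can still be transcribed. A region of METTL3 spanning 21971547 to 21971720, chosen after its values were seen, held 5.53% of METTL3 bin counts in the knockout line and between 8.03% and 9.15% in the other 5 lines. The tests of its 2 bins against the control lines gave log2 fold changes of -0.49 and -0.36, each with an adjusted p of 1.

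**Figure D1:**
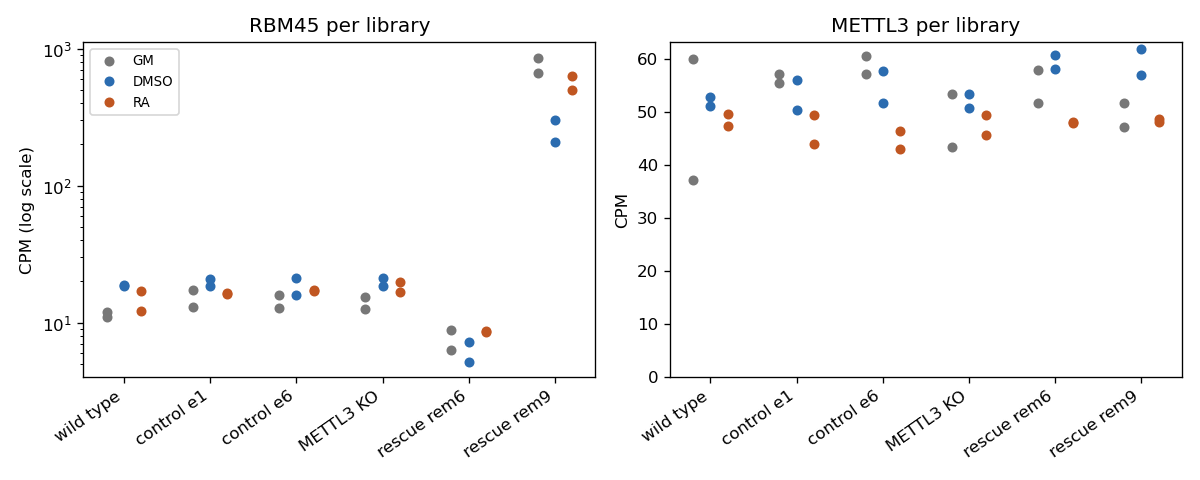
RBM45 (left, CPM on a log scale) and METTL3 (right, CPM) in each of the 36 libraries, by line and medium; each point is 1 library. RBM45 averaged 527 CPM in rescue line rem9 and 7.50 CPM in rem6, while METTL3 averaged 49.3 CPM in the METTL3 knockout line and 52 and 52.8 CPM in the control lines.

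The comparison of RA with DMSO in the 3 lines without a targeted gene (wild type, e1 and e6) asked which genes respond to retinoic acid. The retinoic acid-degrading enzymes CYP26B1 and CYP26A1 and the neurotrophin receptor gene NTRK2 were among the genes with the largest rises. CYP26B1 (ENSG00000003137, chromosome 2, 72356367 to 72375167) averaged 1531 ± 794 CPM in RA and 0.393 ± 0.220 in DMSO (SD, n = 3 lines), a log2 fold change of 11.78 ± 0.40 (SE, adjusted p = 1.23e-07, edgeR quasi-likelihood test). NTRK2 averaged 761 ± 199 CPM against 1.63 ± 0.163, with a log2 fold change of 8.87, and CYP26A1 86.8 ± 30.1 against 0.216 ± 0.252, with 8.85. RGS8 rose by 7.55 on the log2 scale. KRT18, counted together with an overlapping gene, had 1 count in the DMSO libraries, and its RA level rested on wild-type replicate 2, at 62.7 CPM against 0.216 to 3.79 in the other 5 libraries. LINC01587 was at 3.41 CPM in RA and had no counts in DMSO, which makes it at least 49-fold higher (3 counts over the group as the floor). The largest falls were in FRMD1, with no counts in RA and at least 34.8-fold lower, OTOR, with 3 counts in RA and 236-fold lower (95% counting interval 80.4 to 1147), LINC01441, with 1 count in RA and 188-fold lower (33.3 to 7471), the synaptic organiser CBLN4 (-7.47), LINC01440 (-5.50) and the muscarinic receptor CHRM2 (-4.89). CHRM2 averaged 6.23 ± 4.73 CPM in RA and 168 ± 63.9 in DMSO.

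In the same comparison, 12 of 19 measured members of the retinoic acid response list rose and 1 fell, with a median log2 fold change of 2.52 (camera adjusted p = 3.69e-07 with a preset correlation, adjusted p = 0.323 with an estimated correlation). Adjusted over the list alone the counts were also 12 and 1. Of 16 measured protocadherin rows 7 rose, among them PCDHB10 (0.93), PCDHB9 (0.87) and PCDHB14 (0.76), with a list median of 0.68 (camera adjusted p = 1.85e-07, adjusted p = 0.733 with an estimated correlation). These genes are near-identical neighbours, and counting can split their reads. Interferon-stimulated genes rose in 6 of 23, including RSAD2 (2.65), with a median of 0.52 (adjusted p = 0.00108, adjusted p = 0.733 with an estimated correlation). Cholesterol synthesis genes fell in 5 of 24, including SQLE (-0.69), CYP51A1 (-0.72) and LSS (-0.79), with a median of -0.55 (adjusted p = 3.69e-05, adjusted p = 0.733 with an estimated correlation).

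Neuronal lists moved in both directions. Of 25 neuronal cytoskeleton genes, DPYSL3 (3.51) and ELAVL4 (0.79) rose and the growth cone gene GAP43 (-0.77) fell. Of 30 synapse genes 4 rose, among them SYT4 (1.32), SYT11 (0.81) and DLG2 (2.18), and 1 fell. Axon guidance genes fell in 9 of 33 and rose in 3; the netrin receptor UNC5A (-2.36), ROBO2 (-2.17) and SEMA6D (-0.73) were among those that fell. Among 35 channel genes 7 rose, including KCNQ5 (1.58), and 3 fell, including CACNA1G (-2.23). Of 29 adrenergic neuroblastoma identity genes, SCG2 rose (1.62) and 4 fell, among them GATA3 (-1.36) and HAND1 (-0.74). Of 31 mesenchymal markers 6 rose, including COL3A1 (4.68) and RUNX1 (1.75). MYC fell by 4.17 and DUSP6 rose by 1.81 on the log2 scale.

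In total, 1652 genes were higher and 1716 lower in RA among 25734 tested at an adjusted p below 0.05 (edgeR). With libraries as samples, 1273 genes passed within lane 3, which holds wild type and e6. Within lane 4, where e1 was the only line without a targeted gene, 2587 passed. Leaving out library replicate 2 lowered the count to 312, and leaving out e1, e6 or wild type gave 1298, 1378 or 1743.

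The change from GM to DMSO asked what serum-free differentiation medium alone does in the same 3 lines. The signalling inhibitor SMAD6 and the transcriptional regulator ID2 were lower in DMSO. SMAD6 (ENSG00000137834, chromosome 15, 66994566 to 67074338) averaged 0.858 ± 0.763 CPM in DMSO and 93.5 ± 13.6 in GM (SD, n = 3 lines), a log2 fold change of -6.84 ± 0.82 (SE, adjusted p = 0.0022, edgeR). ID2, an inhibitor of basic helix-loop-helix factors, averaged 1.25 ± 0.671 CPM against 49.6 ± 12.1, with a log2 fold change of -5.59. P2RY6 (-6.29) also fell, LINC02769 had 2 counts in DMSO and was 62.7-fold lower (95% counting interval 17 to 524), and S100A10 had no counts in DMSO and averaged 2.45 ± 3.52 CPM in GM, with at most 6.55 in a library. Without wild type S100A10 was not called. The splicing factor gene RBFOX1, counted together with an overlapping gene, fell from 299 ± 70.0 to 10.6 ± 3.27 CPM (log2 fold change -4.76, adjusted p = 0.000212). The largest rises were in LINC02810 (4.36), BHLHE40 (3.87), LINC01441 (3.52), OTOR (3.42), LINC01440 (3.22) and FMNL1-DT (3.08). Without the e6 GM replicate 1 library, described below, their log2 fold changes were LINC02810 5.08, BHLHE40 4.51, LINC01441 4.75, OTOR 6.19, LINC01440 3.96 and FMNL1-DT 4.27, which made OTOR the largest of these 6.

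Cell cycle genes fell in 11 of 36, including the replication helicase genes MCM5 (-1.25) and MCM7 (-0.77) and CDC25A (-0.78). Their median was -0.50 (camera adjusted p = 1.92e-08, adjusted p = 0.733 with an estimated correlation). By line it was -0.97 in wild type, -0.20 in e1 and -0.22 in e6. The e6 GM sum includes the replicate 1 library, described below, that lay among the DMSO libraries. Without that library MCM5 was at -1.46 and MCM7 at -0.92. In the wild-type GM sum the shallow library gave 888754 counts and replicate 2 gave 8371260. Cholesterol synthesis genes rose in 9 of 24, including CYP51A1 (0.93), STARD4 (1.16) and MVD (1.31), with a median of 0.75 (adjusted p = 3.09e-07, adjusted p = 0.733 with an estimated correlation). Splicing regulators fell in 8 of 50 and rose in 1. PTBP2 (-0.61) and SRSF6 (-0.65) fell, and the list median was -0.28 (adjusted p = 2.73e-05, adjusted p = 0.733 with an estimated correlation). The p53 targets CDKN1A (0.95), RRM2B (0.49) and CYFIP2 (0.45) were among 4 of 25 that rose, with a list median of 0.29 (adjusted p = 0.0134, adjusted p = 0.733 with an estimated correlation). Without the e6 GM replicate 1 library the log2 fold change of CDKN1A was 1.80 and that of STARD4 1.84. Of 19 genes of the m6A machinery, IGF2BP3 (-0.71) and METTL16 (-0.41) fell (list median -0.12, adjusted p = 0.0241, adjusted p = 0.733 with an estimated correlation). The adrenergic genes TBX3 (-3.81) and SLC6A2 (-2.33) fell, as did the immediate early genes EGR1 (-2.76) and DUSP2 (-4.23).

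Between GM and DMSO, 1056 genes were higher and 1169 lower in DMSO among 25734 tested (edgeR, adjusted p below 0.05). The e6 GM replicate 1 library lay among the DMSO libraries. On a scale where the GM libraries of wild type and e1 average 0 and their DMSO libraries average 1, it was at 1.01. The remaining GM libraries of the 3 lines lay between -0.114 and 0.0829, and the DMSO libraries between 0.962 and 1.05. Without this library 4822 genes passed. The count was 72 without wild type (4 higher, 68 lower), 167 without e1 (8 and 159) and 1256 without e6 (660 and 596). It was 4033 without library replicate 1 (2130 and 1903) and 0 without library replicate 2. In the latter fit the e6 GM value comes from the library at 1.01 alone. The wild-type GM value comes from the shallowest library alone. This 0 therefore cannot decide whether the change between media recurs. Without line as a block the count was 510 (154 and 356). Within lane 3, which holds the e6 GM replicate 1 library, 0 genes passed with libraries as samples (2803 had an unadjusted p below 0.05). Within lane 4, from e1 alone, 1632 passed.

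**Figure D2:**
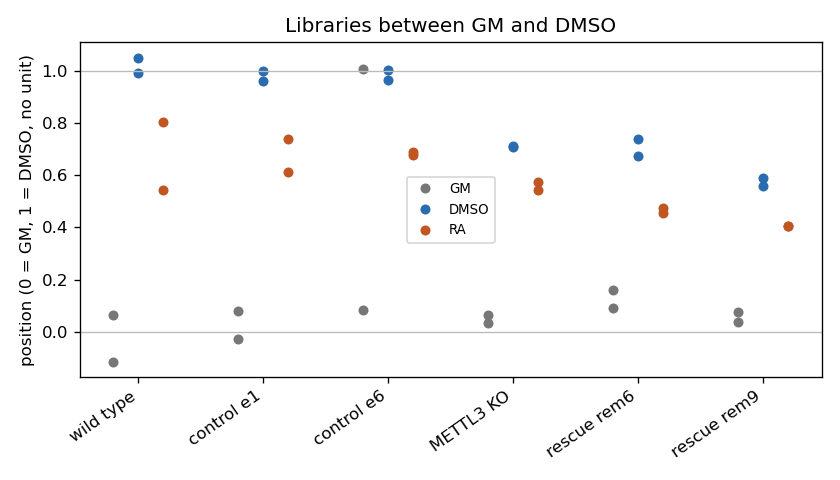
Position of each library between GM (0) and DMSO (1), computed from the 1256 genes that differed between GM and DMSO when line e6 was left out; each point is 1 library, by line and medium, and the scale has no unit. The e6 GM replicate 1 library is at 1.01 and the METTL3 knockout DMSO libraries are at 0.712 and 0.707.

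The lines labelled rescue were compared with the control lines over all media, although only rem9 held more RBM45 RNA than the control lines. RBFOX1 (merged identifier ENSG00000078328 and ENSG00000260411, chromosome 16, 5289803 to 7763340) averaged 0.371 ± 0.113 CPM in the rescue lines and 103 ± 33.3 in the control lines (SD, n = 2 lines), a log2 fold change of -8.03 ± 0.38 (SE, adjusted p = 0.0477, edgeR). ADARB2-AS1 (-7.34) and LINC01414 (-7.13) were also lower, and ZFPM2-AS1 was higher (7.36), at 101 ± 16 against 0.626 ± 0.206 CPM. PDE10A (-4.06), SLC5A7 and ENSG00000215104 completed the 3 higher and 4 lower genes. These last genes fall outside the rule for named genes and were chosen after their values were seen. On simulated data, which also held changed genes, this comparison gave 25 false calls, so the 7 genes may include false ones. The count of 7 was 0 without e1, rem6 or rem9 and 2 without e6. It was 134 without library replicate 1, 1 without library replicate 2, and 0 higher and 3 lower without the e6 GM replicate 1 library, so that ZFPM2-AS1 was not called there. The codes of both rescue lines contain that of 1 knockout clone, whose own libraries were not used here. The tests took the 2 lines as separate units. If both derive from that clone, their spread holds no differences between knockout clones. P-values of all rescue comparisons, exon bins and introns included, may then be too small.

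Mesenchymal markers stood higher in both rescue lines, with a median log2 ratio to the control lines of 1.84 in rem6 and 2.72 in rem9. Over all genes 0 of 32 passed, and 17 were higher adjusted over the list alone (list median 2.18, camera adjusted p = 5.04e-09, adjusted p = 0.733 with an estimated correlation). Interferon-stimulated genes gave 0 over all genes and 11 higher of 24 adjusted over the list alone (median 1.10, adjusted p = 1.77e-07, adjusted p = 0.733 with an estimated correlation). The medians of the cell cycle (-0.35), replication-dependent histone (-0.65), adrenergic (-0.55), neuronal cytoskeleton (-0.56) and synapse (-0.33) lists were below 0, with camera adjusted p-values from 5.37e-07 to 0.0423 and, with an estimated correlation, adjusted p-values from 0.733 to 0.808. The median of the unfolded protein and integrated stress response list was above 0 (0.33, adjusted p = 0.00144, adjusted p = 0.733 with an estimated correlation). The count of 7 genes among 29114 moved with the tool, the filter and the unit of testing, and 4718 genes had an unadjusted p below 0.05. DESeq2 on the same sums called 1515 and edgeR on the same sums without a low-count filter 593. Libraries taken as samples within lane 4, where e1 was the only control line, gave 5488.

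The line labelled METTL3 knockout was compared with the control lines over all media. With edgeR 0 of 29114 genes passed, 955 had an unadjusted p below 0.05, and DESeq2 called 46 (21 higher and 25 lower). Cell cycle genes had a median log2 fold change of -0.43 (camera adjusted p = 6.53e-12, adjusted p = 0.733 with an estimated correlation) and replication-dependent histones one of -0.52 (adjusted p = 8.37e-08, adjusted p = 0.733 with an estimated correlation), with no single member past the test. The p53 target (-0.26, adjusted p = 0.00506) and splicing regulator (-0.12, adjusted p = 0.0216) medians were also below 0, with adjusted p-values of 0.858 and 0.808 with an estimated correlation. A single line was available, assumed to vary like the others. With libraries as samples, 771 genes passed within lane 4, where e1 was the only control line.

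The RA response was then compared between the rescue lines and the 3 lines without a targeted gene, by a test of the difference between the RA-to-DMSO changes. RUNX1 had a log2 RA-to-DMSO change of 5.54 ± 0.200 in the rescue lines (SD, n = 2 lines) and 1.5 ± 0.752 in the others (n = 3 lines). The difference was 4.02 ± 0.58 (SE, adjusted p = 0.00727, edgeR). Since the codes of both rescue lines contain that of 1 knockout clone, the rescue SD may not hold the spread between such clones. NOTCH2 (2.35) and SPARC (2.67) were among the 8 of 31 mesenchymal markers with a higher response (list median 1.49, camera adjusted p = 2.63e-08, adjusted p = 0.733 with an estimated correlation). The dopamine and noradrenaline synthesis genes DDC (-3.69) and DBH (-3.52) and the gene LMO1 (-2.05) were among 4 of 29 adrenergic genes with a lower response (median -1.13, adjusted p = 1.34e-05, adjusted p = 0.733 with an estimated correlation). By line the adrenergic RA-to-DMSO median was -0.53 in rem6 and -1.87 in rem9, against -0.46 in e1, -0.33 in wild type and -0.04 in e6. Cell cycle genes were lower in 3 of 36, namely E2F1 (-1.37), MCM5 (-1.08) and CDC25A (-1.0), with a median of -0.52 (adjusted p = 3.69e-07, adjusted p = 0.733 with an estimated correlation). Of 25 p53 targets CCNG1 (1.23) and RRM2B (0.85) were higher, with a list median of 0.42 (adjusted p = 0.00139, adjusted p = 0.733 with an estimated correlation). Of 25 neuronal cytoskeleton genes ANK3 was higher (1.23) and ELAVL3 (-0.96, counted with overlapping genes) and CRMP1 (-0.81) were lower. The neuronal cytoskeleton (-0.67), synapse (-0.32), channel (-0.29), protocadherin (-0.45) and replication-dependent histone (-0.63) medians were below 0, with camera adjusted p-values from 0.00108 to 0.0114 and, with an estimated correlation, from 0.733 to 0.808.

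The genes with the largest differences toward the rescue lines were ST8SIA6, CFI (7.20), SMOC2, WNT11 (6.46), CDC42EP1 (6.45) and PDGFC (6.05). Toward the other lines they were INSM1, CAPN13 (-4.44), PTPRT (-4.34), FGF6 (-4.21), IGF2-AS (-4.21) and SLC8A3 (-4.12). In 3 of these a few counts set the change: in the rescue lines ST8SIA6 was 1504-fold higher in RA than its 1 count in DMSO (95% counting interval 270 to 59454), SMOC2 202-fold higher than its 2 counts (55.6 to 1673), and INSM1 367-fold lower, with 1 count in RA (65.5 to 14552). In total 583 genes had a higher and 257 a lower response among 25734 tested. The count was 41 without rem9 and 845 without rem6, so that it rested more on rem9. It was 89 without library replicate 2 and 327 without library replicate 1. It was 325 without e1, 334 without e6, 488 without wild type and 0 without line as a block. With libraries as samples, 1967 genes passed within lane 4, where e1 was the only line without a targeted gene.

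**Figure D3:**
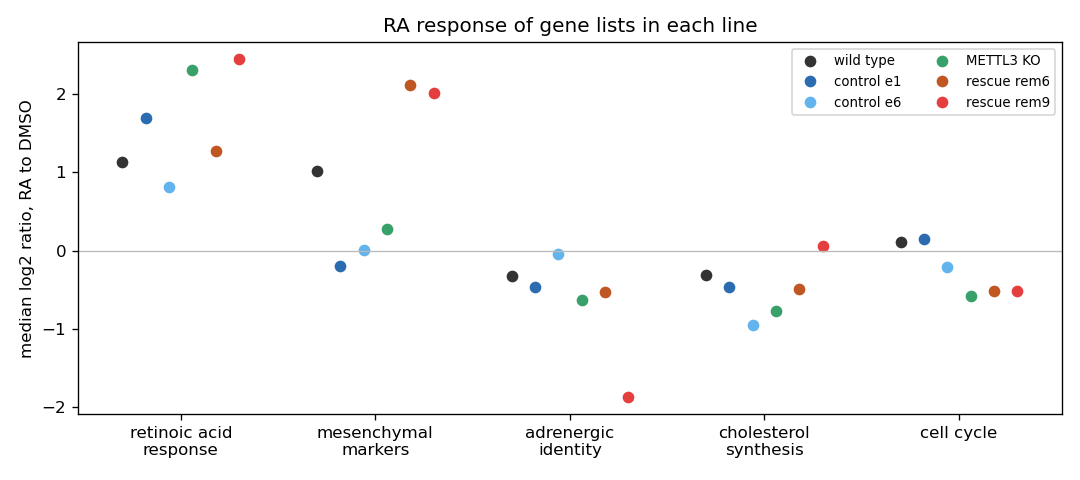
Median log2 ratio of RA to DMSO over the measured genes of 5 lists in each line; each point is 1 line, from the sum of its replicate libraries. The mesenchymal medians of the rescue lines are 2.11 and 2.01 and the highest of the other lines is 1.02 (wild type), and the adrenergic medians are -0.53 in rem6 and -1.87 in rem9, against -0.46 in e1 and -0.63 in the METTL3 knockout line.

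The same test for the METTL3 knockout line called 2 of 25734 genes (1496 with an unadjusted p below 0.05). SLC7A11, the cystine transporter gene, had a log2 RA-to-DMSO change of -3.25 in the knockout line and 0.636 ± 0.122 in the others (SD, n = 3 lines), a difference of -4.06 ± 0.42 (SE, adjusted p = 0.0294, edgeR). Its level in those 3 lines was low, at 0.220 to 1.83 CPM in the DMSO libraries and 0.216 to 3.68 CPM in the RA libraries. Their changes and SD therefore rest on few counts. On simulated data, which also held changed genes, this test gave 3 false calls, so the 2 called genes may be false. ENSG00000204971, which has no symbol and was chosen after its values were seen, had a higher response (5.01, adjusted p = 0.0367). The unfolded protein and integrated stress response list, which contains SLC7A11, had a median of -0.86 (camera adjusted p = 5.21e-14), and the retinoic acid response list one of 1.2 (adjusted p = 7.85e-06). Both had an adjusted p = 0.323 with an estimated correlation. The medians of the cell cycle (-0.61, adjusted p = 7.62e-09), replication-dependent histone (-0.58, adjusted p = 0.00121), splicing regulator (-0.23, adjusted p = 0.015) and neuronal cytoskeleton (-0.29, adjusted p = 0.0228) lists were also below 0, with adjusted p-values from 0.733 to 0.808 with an estimated correlation. By line the retinoic acid response median of RA to DMSO was 2.31 in the knockout line, 2.44 in rem9 and 1.27 in rem6. It was 1.13 in wild type, 1.69 in e1 and 0.81 in e6. The median of DMSO to GM for this list was -0.93 in the knockout line, against 0.38, 0.21 and 0.42 in wild type, e1 and e6. The larger RA-to-DMSO ratio of the knockout line therefore does not by itself show a higher level in RA. The count of genes was 0 without wild type, e6, library replicate 1 or library replicate 2, so that SLC7A11 was not called there, and 4 without e1. DESeq2 called 50 genes, and 107 passed within lane 4, with e1 alone as the line without a targeted gene.

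Exon bins and introns were tested for their use relative to the rest of their gene, since RBM45 is studied here for splicing. In the rescue lines 73 exon bins were used more and 23 less than in the control lines, in 45 genes, among 281605 bins tested. The PCSK7 bin at chromosome 11, 117075053 to 117075789, was higher (log2 2.61, adjusted p = 2.58e-17, edgeR diffSpliceDGE), as were bins of MTUS1 (2.86), VMP1 (1.98, counted with an overlapping gene) and FBXL13 (2.52). A bin of ESRRG had no counts in the rescue lines and 0.453 and 1.47 CPM in e1 and e6, and bins of ALPK1 (-2.11), HSPA8 (-1.51, counted with overlapping small nucleolar RNA genes) and INPP5F (-1.49) were lower. Of 110988 introns, 18 were higher and 17 lower in 23 genes. On simulated data, which also held changed features, the rescue tests gave 26 false calls for exon bins and 33 for introns. Many of the called introns may therefore be false. Introns of MTUS1 (2.96), FBXL13 (2.01), NREP (1.5) and CAPRIN1 (1.37) were among those called higher. Introns of ESRRG (-4.95), KAZN (-3.18), PLEKHA4 (-1.36) and GPC3 (-1.28) were among those called lower. The GPC3 intron itself held 1.80 and 1.53 CPM in rem6 and rem9 and 1.38 and 1.2 in e1 and e6, so that it fell only relative to its gene. Without rem9 14 exon bins and 8 introns passed, and without library replicate 2 they were 23 and 12. In the METTL3 knockout line 1 exon bin was higher, in PDZRN3 (1.15), and 4 were lower, among them a bin of GNAS (-1.67). Another was a bin of a merged gene with BOLA2-SMG1P6 that had no counts in the knockout line or in wild type and 1.45 and 0.349 CPM in e1 and e6. The GNAS bin held 1.09 CPM in the knockout line, 1.16 in rem6 and 1.32 in rem9, against 3.15 in e1 and 10.8 in e6. Its low level was therefore not particular to the knockout line. The PDZRN3 bin held 8.42 CPM in the knockout line, 6.64 in rem9, 3.65 in rem6, 3.89 in e1 and 3.41 in e6. On simulated data, which also held changed bins, this test gave 11 false calls. The count of 5 was 0 without either library replicate, 1 without e6, 1 without the e6 and wild-type GM replicate 1 libraries and 15 without e1; limma's diffSplice called 3 (3 higher and 0 lower), and a minimum of 50 counts left 1, which was higher. For introns 0 passed with edgeR, 753 had an unadjusted p below 0.05, and limma's diffSplice also called 0.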

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

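The tests that weigh explanations below, and their thresholds, were all chosen after the results they concern had been seen. Single libraries were compared with the rest of their group for the targeted genes, the genes with the largest changes, the position between GM and DMSO and the library total, with Dixon's criterion at 95%. Of 180 such tests 20 singled out a library, where chance gives about 1 in 20.

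The library labelled e6, GM, replicate 1 stood apart from the other GM libraries of the wild-type and control lines in 8 tests. It lay at 1.01 between GM (0) and DMSO (1). RBFOX1 was at 6.44 CPM in it, SMAD6 at 1.49, ID2 at 2.64, P2RY6 at 0, OTOR at 7.76 and SLC8A3 at 38 CPM. An exchange with a DMSO library of the same line is argued against, since the lower of the e6 DMSO libraries lay at 0.964 and none was out of place. A DMSO library deposited again is argued against by the chi-square per gene between it and the nearest e6 DMSO library, 3.76, against 2.62 between the e6 DMSO replicates. A wrong medium label or a culture in a DMSO-like state may explain the position of 1.01, and these cannot be told apart because both give the same value.

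RBM45 differed between the rescue lines. It was high in rem9. In rem6 the exon bins before the last held 8.81 CPM, with a fragment counted in each bin it spans, against 9.94 to 11.2 in the control lines. The last bin of rem6 had few counts. Counting error in that bin of rem6 is argued against, since the upper bound of 0.251 CPM lies below the lowest lower bound of the control lines, 0.607. For rem9, 99.9% of RBM45 counts lay outside the last bin, which is consistent with an introduced coding sequence that lacks the end of the gene as the main RBM45 RNA. For rem6 the share of 98.6% leaves this open, because an RNA that ends earlier or a changed locus in the parent clone gives the same share.

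The RA response differed between the rescue lines and the lines without a targeted gene in 840 genes by the test of the difference, and mesenchymal markers were higher in RA than in DMSO in both rescue lines. In DMSO these markers lay below GM, with a median log2 ratio of -1.85 in rem6 and a larger fall in rem9, given under Other observations. The medians of wild type, e1 and e6 were -0.72, -0.37 and 0.03. The RA-to-DMSO ratio alone therefore does not tell a high level in RA from a low level in DMSO. For rem6, sequencing lane is argued against by the difference of the list medians within lane 4, 2.31 between rem6 and e1. For rem9 this cannot decide, since its DMSO replicate 1 library was on lane 3 and its RA libraries were on lane 4. A change in 1 rescue line alone is argued against by the lower of their list medians, 2.01, against 1.02 in wild type, for this list alone. The count of genes was 41 without rem9 and 845 without rem6, so that the calls rested more on rem9, and 89 without library replicate 2. Fibroblast-like cells in the cultures stay open. COL1A2 had 0 counts in the 4 rescue RA libraries, with an upper limit of 0.0673 CPM or 0.00476% of the lowest COL3A1 value, 1414 CPM. It is 1 gene, it was at most 1.09 CPM in any of the 36 libraries, and mesenchymal-type cells of the same line could lack it. The introduced RBM45 and selection of the parent clone may each contribute and remain untested, since the RBM45 knockout libraries were not analysed here.

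The RA response differed between the METTL3 knockout line and the lines without a targeted gene in 2 genes by the same test, and in 0 without wild type, e6, library replicate 1 or library replicate 2. Among the wild-type libraries, DMSO replicate 1 stood apart with RBFOX1 at 18.6 CPM and LINC01414 at 75.6 CPM, DMSO replicate 2 with INSM1 at 1.22 CPM, RA replicate 1 with RBM45 at 12.2 CPM and INSM1 at 1.41 CPM, and RA replicate 2 with S100A10 at 4.32 CPM. The shallow wild-type GM replicate 1 stood apart with METTL3 at 37.1 CPM and a library total of 888754. In e1, LINC01414 was at 107 CPM in GM replicate 2. Among the rescue libraries, RGS8 was at 5.07 CPM in rem6 RA replicate 2, PDGFC at 0.572 CPM in rem6 GM replicate 1 and FMNL1-DT at 0.628 CPM in rem9 GM replicate 2. Outside the main measurement, intron-table counts on an unplaced scaffold with ribosomal RNA reached 5556640 in wild-type GM replicate 1, and the next highest value was 1836520 (METTL3 knockout, GM, replicate 1).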

How the results depend on the processing

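Alternatives for the RA responses of the rescue and METTL3 lines, for exon bins and introns of the rescue lines, by lane, and without the e6 or wild-type GM replicate 1 library were chosen after seeing the data. Causes of the moves below were not tested. Counts are genes past the threshold, in the order of the report: RA against DMSO 3368, DMSO against GM 2225, rescue against control 7, METTL3 against control 0, and RA response of the rescue lines 840 and of the METTL3 line 2.

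DESeq2 gave 1515 (rescue), 46 (METTL3), 1394 and 50 (RA responses). Without a low-count filter the counts were 593 (rescue), 1518 and 25 (RA responses). With libraries as samples they were 5106 (RA against DMSO), 3509 (DMSO against GM), 7256 (rescue), 1193 (METTL3), 2474 and 49 (RA responses). With the spread between replicate libraries of a line they were 5303, 4238, 8203, 2504, 2920 and 155 in that order. Both count libraries of a line as separate samples. Without line as a block the counts were 1637 (RA against DMSO), 510 (DMSO against GM), 0 and 0 (RA responses). Adding wild type to the controls gave 248 (rescue), and limma-trend on mean log2 CPM gave 0. Within lane 4, where e1 was the only line without a targeted gene, the counts were 5488 (rescue), 771 (METTL3), 1967 and 107 (RA responses). Within lane 3 they were 1273 (RA against DMSO) and 0 (DMSO against GM). Without the e6 GM replicate 1 library they were 4822 (DMSO against GM) and 3 (rescue), and without it and the shallow wild-type library 4612 and 3.

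Leaving out each line or replicate number gave 312 to 2929 genes for RA against DMSO, 0 to 4033 for DMSO against GM (72 without wild type, 167 without e1, 1256 without e6, 4033 without replicate 1, 0 without replicate 2), 0 to 134 for rescue, 0 to 0 for METTL3, and 41 to 845 and 0 to 4 for the RA responses. Where an arm is left with 1 line, it is assumed to vary like the others. The range was 14 to 119 exon bins and 8 to 52 introns for rescue, and 0 to 15 and 0 to 13 for METTL3.

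Signs turned for RBM45 in rescue without rem9 (range -1.16 to 4.90), METTL3 in the METTL3 line without replicate 1 (range -0.145 to 0.00838), RBM45 in the METTL3 line without replicate 2 (range -0.00377 to 0.178), METTL3 in DMSO against GM without replicate 2 (range -0.104 to 0.00702), and RBM45 in the RA response of the METTL3 line without replicate 2 (range -0.0289 to 0.261); none passed a test where its sign had turned. RBM45 in rescue passed with libraries as samples, with the spread between replicate libraries and with the replicate number as a block. Of the alternatives for named genes, 842 of 1022 kept direction and call for RA against DMSO, 654 of 907 for DMSO against GM, 85 of 114 for rescue and 521 of 741 for the RA response of the rescue lines.

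For exon bins of the METTL3 line (5), voom gave 3, a minimum of 50 counts 1, and leaving out both GM libraries 1. For the rescue lines voom gave 164 exon bins and 69 introns, the minimum of 50 counts 47 and 17, and wild type among the controls 248 and 87. With an estimated correlation camera called 0 lists in each of the 6 comparisons, against 4 to 9 with the preset one.

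Replicate numbers were not taken to pair the libraries: the difference of replicates 1 and 2 correlated at -0.072 to 0.252 between media of a line (6 of 18 above 0.1) and at -0.463 to 0.378 between lines (21 of 135). With the replicate number as a block, and libraries as samples, the counts were 3345 (DMSO against GM), 7257 (rescue), 1130 (METTL3), 2372 and 37 (RA responses).

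With 10 splits of the line sums a share below 0.05 cannot be reached. The real split gave 3368 genes for RA against DMSO and the highest other 1, and 2225 against 2 for DMSO against GM; in each case 1 split, the real one, gave as many. Comparisons of RBM45 knockout clones with control and rescue clones, their RA response, exon bins, introns, overlap with METTL3 and reversal by rescue were planned and not run. Depth limits the wild-type GM replicate 1 library most. The medians of the 2 tested abundant non-polyadenylated RNAs were -0.88 for RA against DMSO and 0.91 for DMSO against GM. For the RA response of the rescue lines the median was 1.72. In each of these comparisons 1 of the 2 passed. Otherwise the medians were -0.126 (rescue), -0.61 (METTL3) and 0.81 (RA response of the METTL3 line), and 0 passed. What moved these values was not tested.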

Other observations

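The METTL3 knockout and rescue lines moved less far from GM toward DMSO than the lines without a targeted gene, on the scale of 1256 genes chosen without e6. DMSO libraries lay at 0.712 and 0.707 in the METTL3 knockout line, 0.672 and 0.737 in rem6, and 0.558 and 0.591 in rem9, against 0.962 to 1.05 in the wild-type and control lines. RA libraries of the wild-type and control lines lay between 0.542 and 0.803. The genes were chosen in wild type and e1, which places these 2 lines at the ends of the scale, while e6 played no part in the choice and its DMSO libraries lay at 1.00 and 0.964. The difference between lines was not tested.

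Mesenchymal markers had a median log2 ratio of DMSO to GM of -1.85 in rem6 and -2.40 in rem9, against -0.72 in wild type, -0.37 in e1, 0.03 in e6 and -0.67 in the METTL3 knockout line. The e6 GM sum includes the replicate 1 library, which lay at 1.01 between GM and DMSO, so the e6 median may not measure the full change between these media. The difference between the rescue lines and the others was not tested. These DMSO levels are also the base of the RA-to-DMSO ratios of the same markers given above.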
